A study of Homo sapiens with 10 samples.

How the data were processed

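HSF1 ChIP-seq was analysed from 6 peak lists of HCT116 colon cancer cells, each from chromatin precipitated with 5 µg of an antibody to HSF1, per the labels. Groups and replicate numbers came from the sample titles: KO and WT cells, untreated or heat shocked at 42 °C for 1 h. The series also names 4 input libraries, 1 for each line and condition, which were not used here.

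Each list has 5 columns: chromosome, start, end, a peak name and a score. CASAVA, Bowtie 0.12.7, MACS 1.4.2 and the build hg19 are named in the submitters' processing notes, without roles or settings. Peaks carry MACS names and each list was called for a single library against the input of its own line and condition, per the file labels. Scores are the authors' deposited peak scores. Their lowest values were 50.0 to 50.44 in each list, as would be seen for a negative log10 p-value multiplied by 10, but this is a reading of the values and is not stated. Scores were used to rank peaks within a list, to filter every list at a score of at least 100 and to choose the regions named. The last uses set scores of several libraries side by side, and these depend on the unknown depth, so counts of filtered peaks describe the lists and not binding strength. No fold enrichment, tag count or read depth was used here, so the depth of each library is unknown. A region missing from a list fell below the caller's limit in that library, which is not evidence that HSF1 was absent. Called peaks also depend on depth and on the width over which the caller pooled reads. The narrowest peak was 59 to 63 bp in the KO lists and 561 to 714 bp in the WT lists, and 97.0 to 98.3% of the peaks of each KO list were narrower than the narrowest WT peak. Peak numbers of the lines were thus not obtained at one resolution, and covered length is given beside them. Covered length is affected as well. At the 37 regions with a peak in all 6 lists, the WT peak was wider at 37, by a median of 2.36-fold. Covered length thus counts more sequence per region in WT, which lowers the ratio of KO to WT.

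Peaks were counted as listed. Mean log2 ratios of peak number were formed between groups, with an exact permutation test (two-sided) where both groups had 2 libraries, that is for KO against WT after heat shock. The untreated groups have 1 library each, so the other comparisons have values for each replicate and no test; the fold between the untreated lists has an exact counting interval. Lists were compared by overlap of at least 1 bp, counted with numpy 2.4.6 and checked against bedtools 2.31.1, with exact Clopper-Pearson 95% intervals from scipy 1.17.1. Each overlap was tested one-sided against 1000 random placements of the shorter list within its chromosomes, between the first and last peak of any list, with Benjamini-Hochberg adjustment over the 15 pairs; assembly gaps were not left out, since no genome was used. Overlapping peaks of the 6 lists were joined into regions, and a region counted for a group if any of its libraries had a peak. Shares of regions on parts of chromosomes were compared with Fisher's exact test (two-sided, Benjamini-Hochberg over 10 tests), and shifts in rank between KO lists with a permutation test (two-sided, 100000 permutations). Tables were handled with pandas 2.3.3 and figures drawn with matplotlib 3.10.9, under Python 3.11.15.

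Overlap counting, region building and the placement test were tested on 20 simulated pairs of lists with the lengths of WT heat shock replicate 1 (225 peaks) and KO heat shock replicate 1 (1566 peaks). With 50 shared peaks planted, counts equalled a direct count in 20 of 20 pairs and the test called 20. With none planted it called 0. The simulated peaks were placed at random as in the test itself. They therefore check the counting, and not whether random placement suits real peaks.

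Regions were named by a rule set, like the planned comparisons and settings, before the data were examined: in each comparison, up to 10 regions with a peak in every library of one group and none of the other, or in every library of both, by the highest score of the lower-scoring library, plus small sets of 4 or fewer regions, and the example of a weak region found in all 6 lists, chosen after their values were seen. The annotation at hand is of another build (GRCh38), so no gene, promoter or sequence motif was assigned to any region. Regions were also not screened for repeats or artefact signal. The 13 gene lists fixed beforehand, the share of peaks at promoters and the search for heat shock elements were therefore not computed. Settings tried in turn were a score of at least 100, peaks closer than 1000 bp joined, chromosomes 1 to 22 and X, peaks without the widest 5%, other definitions of a shared peak, other random placements, a peak required in both replicates, a replicate block, and each heat shock library left out. Covered length in place of peak number, joining within 2000 bp, the number of regions found in both replicates and placement within 1000000 bp were added after seeing the data.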

Results

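HSF1, the transcription factor that drives the heat shock response, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in HCT116 cells, an established human colon cancer line. The cells were unmodified (WT) or lacked FBXW7 (KO), the subunit of a ubiquitin ligase that recognises proteins to be degraded. Each line was left untreated or held at 42 °C for 1 h. The comparisons ask where HSF1 sits on the genome in each line at rest, and how its peaks differ after heat shock and between the lines. There were 6 HSF1 libraries: 2 of WT heat shock, 1 of untreated WT, 2 of KO heat shock and 1 of untreated KO. The lists held 225 and 131 peaks in WT heat shock replicates 1 and 2, 79 in untreated WT, 1566 and 3257 in KO heat shock replicates 1 and 2, and 2866 in untreated KO. Read depth is unknown for all 6, and peak scores are the authors' own values, used here to order and filter peaks; they are not known to be on one scale across libraries. Positions are hg19. Peaks were not screened here for repeats or artefact signal, so a named region is not shown to be an HSF1 site. Nothing in the labels says that replicates came from separate cultures, so the spread between them may be technical.

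**Figure D1:**
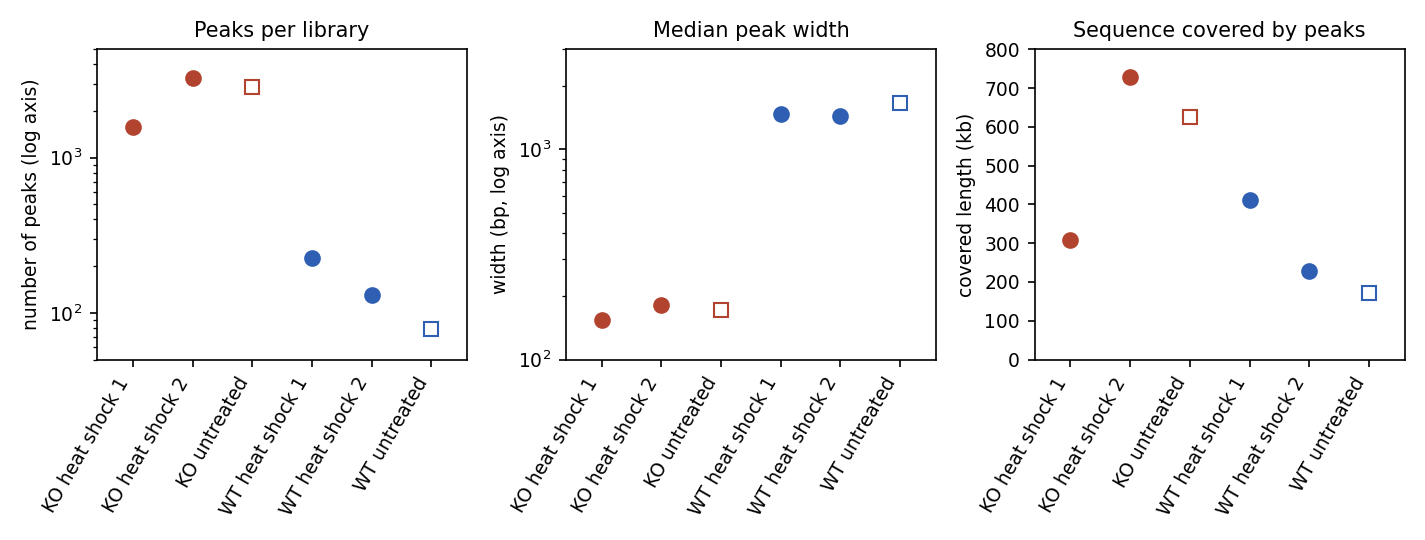
Number of peaks (log axis), median peak width in bp (log axis) and covered length in kb for each of the 6 HSF1 libraries, 1 point per library (red KO, blue WT, filled circles heat shock, open squares untreated). The 3 KO lists held 1566 to 3257 peaks with median widths of 155 to 181 bp, and the 3 WT lists 79 to 225 peaks with median widths of 1443 to 1656 bp.

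A small set of regions carried an HSF1 peak in every library, most of them among the strongest of each list. Joining overlapping peaks of the 6 lists gave 6597 regions, and 37 of them had a peak in all 6. The region chr2:198363695-198365679 had the highest score of all 3 WT lists and of KO heat shock replicate 1 (872, 892, 663 and 2700 in WT heat shock replicates 1 and 2, untreated WT and that KO library), shared the highest score of the untreated KO list (3100) and shared the second rank in KO heat shock replicate 2. In these last 2 lists its score was exactly 3100, as were those of chr14:102552691-102554346 and chr19:1353842-1355364. This value may therefore be a cap, and ranks at or next to it may not order the regions. The regions chr14:102552691-102554346, chr13:31190920-31192725 and chr13:34116222-34117822 ranked between 1 and 6 in each of the 6 lists. Also found in all 6 were chr13:31734751-31737082, chr19:1353842-1355364, chr6:44213452-44216301, chr17:16283375-16285056 and chr12:133286374-133287943. Another, chr1:142535218-142540183, was 4966 bp long, and its KO and WT peak centres lay 810 bp apart. It ranked 6, 6 and 10 in WT heat shock replicates 1 and 2 and untreated WT. Its ranks were 40, 105 and 129 in KO heat shock replicates 1 and 2 and untreated KO. The median rank of the 37 regions lay between 22 and 27 in every list, and 24 to 27 of them were among the 37 highest scores of each list. A few were weak in the KO lists, such as chr1:234911754-234919464 (ranks 1004, 582 and 789 in KO heat shock replicates 1 and 2 and untreated KO). Peak centres of the lines lay close together at these regions, a median of 49.2 bp apart and within 200 bp at 29 of the 37, while the WT peak was wider at 37 of 37 (median widths 1491 and 606 bp). At the other end, 5867 regions (88.9%) had a peak in 1 library only, 5718 of them in a KO library.

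**Figure D2:**
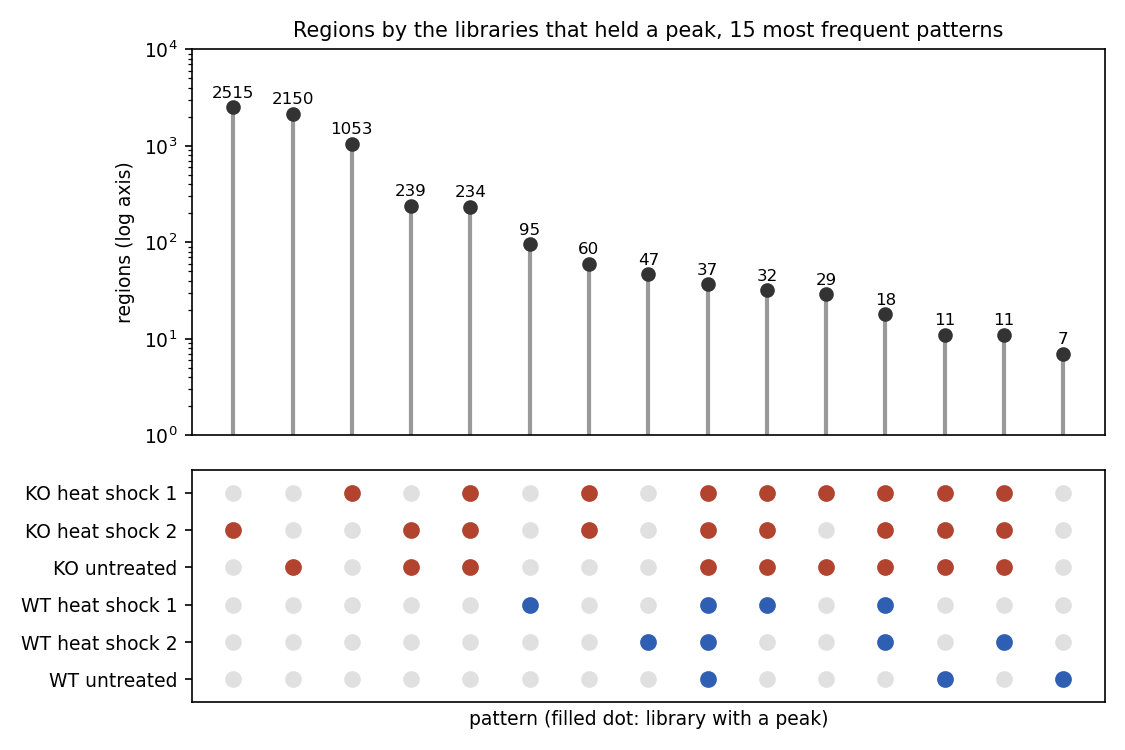
Number of regions (log axis) for each of the 15 most frequent combinations of libraries with a peak; filled dots below mark the libraries (red KO, blue WT). The 3 most frequent combinations are a single KO library each (2515, 2150 and 1053 regions), 234 regions had a peak in all 3 KO lists and no WT list, and 37 in all 6.

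In WT cells, both heat shock lists were longer than the untreated list, 2.85-fold in replicate 1 and 1.66-fold in replicate 2. Peaks of no other list made up 95 of 225 and 47 of 131 in replicates 1 and 2, against 7 of 79 untreated. Of these, 73 of 95, 40 of 47 and 7 of 7 lay in 13 windows on parts of a few chromosomes, described below. The windows were chosen on such regions, which raises these shares. The longer lists are therefore not shown to be HSF1 peaks gained on heat shock. There were 238 regions with a peak in at least 1 heat shock replicate and none in the untreated list, 25 in the untreated list alone and 54 in both conditions, which sets 2 lists against 1. With a peak required in both replicates the order turned, to 23 regions of heat shock alone and 40 of untreated alone. That rule counts a region with a peak in 1 heat shock replicate as untreated alone, and 25 of the 40 had a peak in neither. It can only lower the first count and raise the second, so the turned order says nothing about binding. The highest scores among the 23 were at chr19:50528618-50529869 (127 and 137 in replicates 1 and 2), chr12:125398564-125400665 (150 and 126), chr3:75695233-75700225 (106 and 113) and chr2:91813895-91819614 (148 and 95.2). Those on chromosomes 19 and 12 ranked between 16 and 46 in the KO lists. Those on chromosomes 3 and 2 were 4993 and 5720 bp long. Their ranks in KO heat shock replicates 1 and 2 and untreated KO were 1504, 428 and 348, and 239, 573 and 697. Whether repeats gave such peaks was not tested. Of these 23 regions, 20 had a peak in the untreated KO list and 19 in both KO heat shock lists, and 2 in no KO list. Of the 25 regions of untreated WT alone, the leaders were chr10:42354717-42360011 (score 90.2), chr19:18740107-18741446 (77.9), chr1:16161151-16163151 (71.9) and chr12:57080798-57083104 (71.1), and the last 3 had a peak in all 3 KO lists. A further 39 regions had a peak in all 3 WT lists. The mean log2 ratio of peak number was 1.12 (replicates 1.51 and 0.73, SD 0.55, n = 2 against 1 library), with no test because untreated WT has a single library. Without replicate 1 the regions of heat shock alone numbered 86.

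In KO cells, heat shock lists fell on either side of the untreated list, at 0.546-fold (replicate 1) and 1.14-fold (replicate 2) of its 2866 peaks. The mean log2 ratio of −0.34 was smaller than the spread between the replicates (SD 0.75, n = 2), and became 0.18 without replicate 1. There were 3644 regions with a peak in at least 1 heat shock list and none in the untreated list, 2158 in the untreated list alone and 641 in both, which sets 2 lists against 1. With a peak required in both replicates there were 66 of heat shock alone, 2444 of untreated alone and 355 of both. This turn of the order is again set by the rule, and 2158 of the 2444 had a peak in neither heat shock replicate. Without replicate 2 the order turned as well (1123, 2412 and 387). Of the 421 regions with a peak in both heat shock replicates, 355 (84.3%) were also in the untreated list and 66 were not. The 66 were led by chr8:145515377-145515603 (scores 399 and 248 in replicates 1 and 2), chr10:70450203-70451856 (718 and 194) and chr8:18924860-18925181 (146 and 181), and included chr10:70446094-70446475 (314 and 94.1). WT lists held 6 of the 66. Among the regions of the untreated list alone, scores were highest at chrY:58992124-58992635 (248), chr7:148224599-148225014 (239) and chr21:9826670-9827605 (189), and 2150 of the 2158 were in no other list. Of the 6597 regions, 1 had a peak in all 4 heat shock lists and in neither untreated list. This was chr10:70450203-70451856, with scores of 73.3 and 84.7 in WT heat shock replicates 1 and 2. Untreated KO has a single library, so the KO comparison has no test.

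Without heat shock, the KO list held 36.3-fold as many peaks as the WT list (2866 against 79; log2 ratio 5.18; exact 95% interval of the fold from counting error 29.0 to 46.0). KO peaks were narrower, with a median of 173 against 1656 bp, and the covered length differed less, at 626 against 171 kb (3.65-fold). The wider WT peaks lower this last ratio. Most WT regions were part of the KO list: 67 of 79 had a peak in both, 12 in WT alone and 2732 in KO alone. The strongest regions of KO alone were chr11:63952261-63954313 (score 1358), chr19:50528618-50529869 (1206), chr22:29664109-29664977 (1199), chr5:133706413-133707057 (1061) and chr17:62703132-62703813 (1017); the first and second of these had a peak in both WT heat shock lists. Of the 2732 regions, 80 had a peak in a WT heat shock list. The strongest region of WT alone was chr11:118342003-118345571 (score 397, second in its list), which had a peak in WT heat shock replicate 1 (64.4) and in no KO list. It was followed by chr4:49104105-49108377 (74.3), found in all 3 WT lists and no KO list. Repeats were not screened out, so these regions are not shown to be HSF1 sites of WT alone. With 1 library per line there is no replicate check, and the interval covers counting error only.

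After heat shock, each KO list was longer than each WT list, by 6.96-fold to 24.9-fold. The ratio of geometric means was 13.2-fold (log2 ratio 3.72; 2412 ± 1196 against 178 ± 66.5 peaks, SD, n = 2 each; exact permutation test, two-sided, p = 0.333, the smallest that 2 libraries against 2 can give). Covered lengths overlapped between the lines, at 308 and 728 kb in KO and 412 and 227 kb in WT (log2 ratio 0.63; exact permutation test, two-sided, p = 0.667). Median widths were 155 and 181 bp in KO and 1468 and 1443 bp in WT. The wider peaks raise the covered length of WT, so its overlap between the lines does not show equal numbers of sites. By regions, 4146 had a peak in at least 1 KO and no WT heat shock list, 153 the reverse, and 139 had a peak in both lines. Leaving out KO replicate 2 gave 1389 regions of KO alone, and leaving out WT replicate 1 gave 52 of WT alone and 78 of both. With a peak required in both replicates, KO had 421 regions and WT 62, of which 56 were common.

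Of the 421 KO heat shock regions, 305 had no peak in either WT heat shock list, and 245 of these 305 were also present in untreated KO. The leaders were chr22:29664109-29664977 (scores 703 and 1553 in KO replicates 1 and 2), chr17:62703132-62703813 (396.5 and 631), chr19:18740107-18741446 (388 and 1070), chr12:57080798-57083104 (355 and 799) and chr1:174968915-174969476 (342 and 592). Untreated WT held 11 of the 305, among them the regions on chromosomes 19 and 12 just named. Conversely, 4 regions had a peak in both WT heat shock lists and in neither KO heat shock list: chr12:162326-167873, chr21:11185744-11187341, chr4:49104105-49108377 and chr10:114755699-114758206. The 56 regions of all 4 heat shock lists were led by chr2:198363695-198365679, and 55 of them had a peak in untreated KO and 37 in untreated WT. Taking all conditions, 234 regions had a peak in all 3 KO lists and no WT list, and 2 the reverse (chr12:162326-167873 and chr4:49104105-49108377).

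Each pair of lists shared more peaks than random placement gave. Of the 79 untreated WT peaks, 84.8% (95% interval 75 to 91.9) overlapped a peak of untreated KO, 62.0% one of WT heat shock replicate 1 and 55.7% one of replicate 2. These shares compare lists of 79 to 3257 peaks. Among the 79 highest-scoring peaks of each list, those of untreated WT were found in untreated KO at 53.2% (41.6 to 64.5) and in the WT heat shock lists at 50.6% (39.1 to 62.1) and 45.6% (34.3 to 57.2). WT heat shock peaks were found in the KO heat shock lists at 46.7 to 59.5%, and 48.1% (39.3 to 57.0) of replicate 2 peaks were found in replicate 1. Among the 79 highest, WT replicate 2 peaks were found in WT replicate 1 at 58.2% (46.6 to 69.2) and in KO heat shock replicates 1 and 2 at 46.8% (35.5 to 58.4) and 44.3% (33.1 to 55.9); these intervals overlap, and the differences were not tested. Of the 1566 peaks of KO heat shock replicate 1, 29.6% (27.3 to 31.9) were in replicate 2 and 26.4% (24.3 to 28.7) in untreated KO. Of the 3257 peaks of KO heat shock replicate 2, 19.7% (18.4 to 21.1) were in untreated KO and 13.8% (12.6 to 15) in replicate 1. Random placement within chromosomes gave at most a mean of 0.435%, and the adjusted permutation p was 0.001 for each of the 15 pairs, the smallest that 1000 placements can give. Placement within 1000000 bp gave a mean of up to 1.07%, for WT heat shock replicate 1 in KO heat shock replicate 2. Intervals are exact binomial and cover counting error only. These tests compare lists, not conditions. Random placement ignores features that all lists may share, such as repeats, so they do not show shared HSF1 binding.

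**Figure D3:**
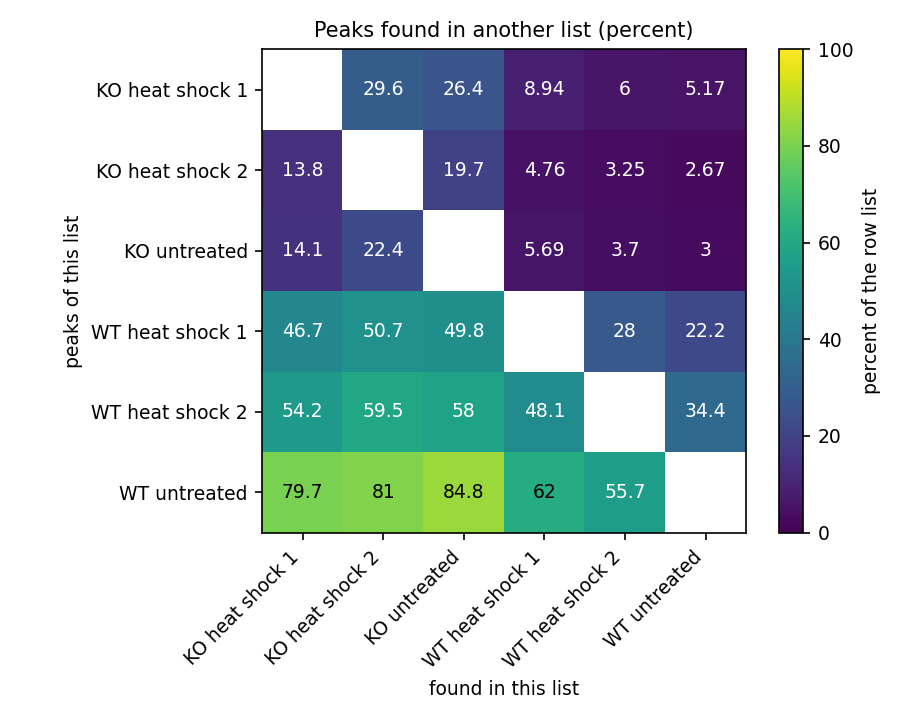
Percent of the peaks of each list (rows) that overlap a peak of another list (columns) by at least 1 bp, for the 6 HSF1 libraries. Untreated WT peaks were found in the KO lists at 79.7 to 84.8%, and KO peaks in the WT lists at 2.67 to 8.94%.

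High-scoring KO peaks recurred in other lists more often than low-scoring ones. Among peaks of KO heat shock replicate 2 with scores of 50 to 75 (2477 peaks), 62 were in replicate 1 and 31 in WT heat shock replicate 1. Between 200 and 500 the shares were 88.4% and 13.7% (of 146), and at 1000 or more 100% and 86.2% (of 29; 95% interval of the last 68.3 to 96.1). Untreated KO peaks with scores of 1000 or more were found in untreated WT at 82.8% (24 of 29). In the other direction, WT heat shock replicate 1 peaks with scores of 100 to 200 were found in each KO list at 91.4% (32 of 35), and those of 50 to 75 at 30 to 35% (of 140). Peaks of no other list made up 67.2, 77.2 and 75% of KO heat shock replicates 1 and 2 and untreated KO, and 42.2, 35.9 and 8.86% of WT heat shock replicates 1 and 2 and untreated WT.

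**Figure D4:**
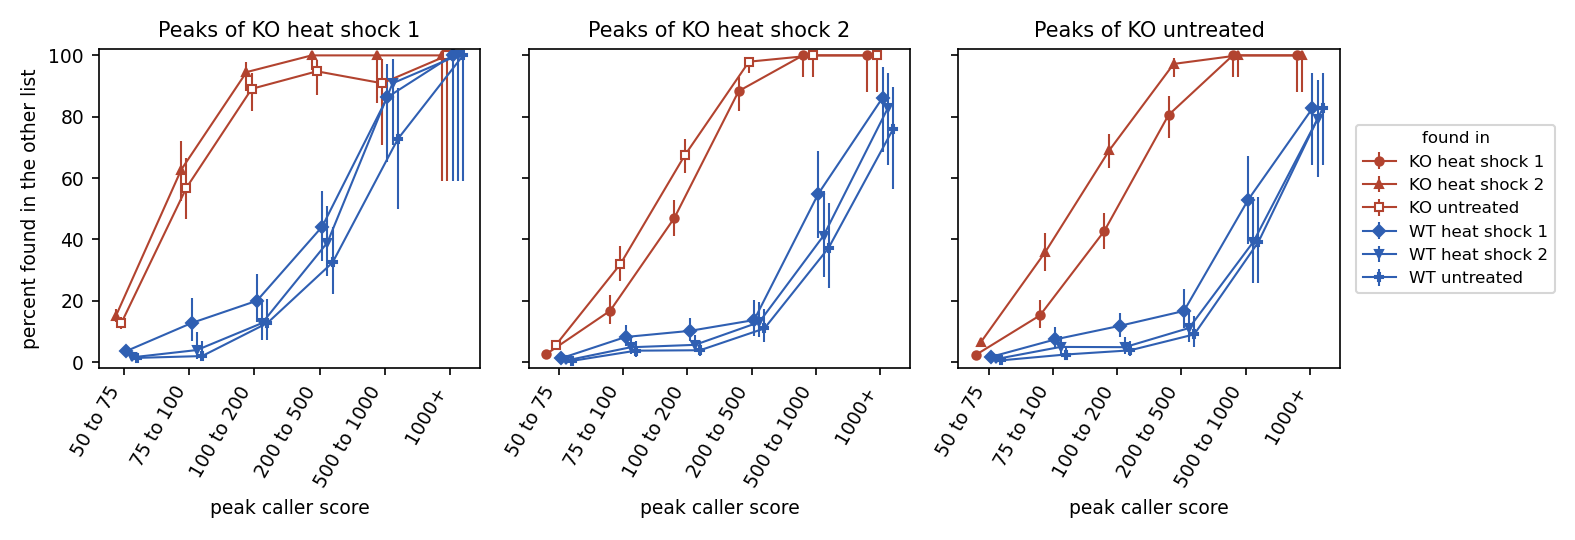
Percent of the peaks of each KO list found in each of the other 5 lists, by peak caller score (bins on the x axis); points are shares and bars exact 95% binomial intervals (red KO, blue WT, open squares untreated KO). In KO heat shock replicate 2, the share found in WT heat shock replicate 1 is 10.2% at scores of 100 to 200 and 86.2% at 1000 or more.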

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

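Of the tests in this part, joining peaks within 2000 bp, counting regions of both replicates, covered length, the share by score and the lists of 200, 500, 1000 and 1500 peaks were chosen after the results were seen; the lists of 79 peaks were planned, and both tests of exchanged labels were set before theirs.

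Peaks with a score of at least 100 numbered 48 and 28 in the WT heat shock lists against 24 in untreated WT, and 216 and 511 in the KO heat shock lists against 512 in untreated KO. Both WT lists thus lay above and both KO lists below their untreated list, but KO replicate 2 by 1 peak, so that the KO difference rests on replicate 1. WT replicate 2 was also close to its untreated list (28 against 24), so the WT difference rests mostly on replicate 1 (48). The difference between the lines was not tested.

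KO lists held more peaks than WT lists after heat shock, at a log2 ratio of 3.72. Narrow peaks that split a site into several entries are argued against as the whole cause, since the ratio was 3.70 after peaks within 2000 bp were joined, and so are weak entries that do not recur, since regions of both replicates gave 2.76 (421 against 62, or 6.79-fold). Sequencing depth, enrichment or the calling window may still account for it, and cannot be told apart from the line: the share of KO replicate 2 peaks found in WT replicate 1 rose by 76.0 percentage points between scores of 100 to 200 and of 1000 or more, which weaker HSF1 occupancy in WT would give too. Every WT peak was at least 561 bp wide and 97.0 to 98.3% of the peaks of each KO list were narrower. On covered length, which the wider peaks raise in WT, the log2 ratio was 0.63. A change of HSF1 binding through loss of FBXW7 stays open and was not tested apart from these.

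KO heat shock replicate 2 shared more peaks with untreated KO (19.7%) than with KO heat shock replicate 1 (13.8%). The length of the list of replicate 1 is argued against as the whole cause, since at equal lengths the shares were 66.0% (95% interval 61.7 to 70.1) and 56.4% (51.9 to 60.8) among the 500 highest-scoring peaks of each list, 48.2% (45.1 to 51.3) and 37.6% (34.6 to 40.7) among the 1000 highest and 36.3% (33.8 to 38.8) and 28.9% (26.6 to 31.3) among the 1500 highest. Weaker signal in replicate 1, which has 216 peaks with scores of at least 100, may still account for it, since its 500 highest reach into weaker peaks and the intervals overlapped among the 200 highest (79.5%, 73.2 to 84.9, and 75%, 68.4 to 80.8) and the 79 highest (81.0% and 78.5%). Exchanged labels stay open: 18 regions of both WT heat shock lists and not untreated WT stood higher in the KO heat shock lists than in untreated KO, relative to 60 regions of untreated WT, which an exchange would not give (7.75 ranks among 355 regions in replicate 1, higher in 12 of 18; permutation test, two-sided, p = 0.012, adjusted p = 0.0239; 6.25 ranks in replicate 2, higher in 11 of 18; p = 0.16, adjusted p = 0.16), but these p cover the spread among regions of 1 library against 1, and not that between libraries. No biological explanation was tested, since the labels give none for a difference between replicates.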

How the results depend on the processing

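Covered length, joining within 2000 bp, regions of both replicates as a ratio and placement within 1000000 bp were chosen after seeing the data; the other settings were planned.

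With scores of at least 100, peaks numbered 216, 511 and 512 in KO heat shock replicates 1 and 2 and untreated KO and 48, 28 and 24 in the WT lists in that order, and the log2 ratio of KO to WT untreated was 4.42. Regions of heat shock alone, untreated alone and both were then 35, 7 and 17 in WT and 177, 156 and 339 in KO; regions of KO alone, WT alone and both were 473, 9 and 43 after heat shock and 472, 1 and 23 untreated. These fell because fewer peaks entered. With a peak required in both replicates, WT had 23 regions of heat shock alone and 40 of untreated alone, and KO had 66 of heat shock alone and 355 of both. KO against WT after heat shock gave 365, 6 and 56. Under this rule a group lacks a region that has a peak in only 1 of its replicates. Of the 365, 305 had no WT heat shock peak, and 4 of the 6 had no KO heat shock peak.

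Leaving out each heat shock replicate in turn gave 86 to 175 regions of heat shock alone in WT, and 1123 to 2587 of heat shock alone and 387 to 609 of both in KO. For KO against WT after heat shock it gave 1389 to 4207 regions of KO alone, 52 to 171 of WT alone and 78 to 134 of both. The log2 ratio of heat shock to untreated in KO ran from −0.87 to 0.18 and so changed sign without replicate 1; the cause was not tested. That ratio ran from 0.73 to 1.51 in WT, and KO against WT after heat shock from 3.19 to 4.25.

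Covered length in place of peak number gave log2 ratios of 0.84 (WT heat shock), −0.40 (KO heat shock), 0.63 (KO against WT, heat shock) and 1.87 (KO against WT, untreated, where peaks of KO are narrower). With a replicate block, the log2 ratio of KO to WT after heat shock was 3.72, which the balanced design fixes, so it says nothing about stability. The labels do not say whether same-numbered libraries were processed together. The correlation of their deviations was 0.024 over 6597 regions, which cannot tell, since 88.9% of regions had a peak in 1 library only. All 90 overlaps (15 pairs, 6 settings) stayed above random placement, with adjusted p of at most 0.001, the smallest that can be given. Random placement gives so few overlaps that this outcome says little about stability. The shares themselves moved: from 22.4 to 84.8% of the shorter list they went to 58.3 to 95.8% with scores of at least 100 and to 41.8 to 81.0% among the 79 highest. KO heat shock replicate 1 in replicate 2 went from 29.6 to 91.2 and 78.5%, untreated KO in KO heat shock replicate 2 from 22.4 to 65.4 and 81.0%, and untreated WT in untreated KO from 84.8 to 95.8 and 53.2%. Joining peaks within 1000 bp, leaving out chromosome Y and leaving out the widest 5% were run on the peak numbers of the 6 lists and moved none by over 1.5 times. Leaving out the widest 5%, or chromosome Y with at most 4.89% of a list, could not move a number that far. Of these settings, only the joining was also run on the log2 ratios. Counting peaks within 500 bp as shared moved none of the region counts by over 1.5 times. Alternatives for promoters, gene lists and heat shock elements were not run. Unknown read depth limits every difference in peak number.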

Other observations

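The windows chosen on WT regions and the share on chromosome 19 were set as tests before their results were seen; the start of chromosome 1, the comparison outside the windows and the windows by chromosome were chosen after.

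A pair of nearby regions on chromosome 10 had peaks in heat shock lists only, where each untreated group has 1 library. Besides chr10:70450203-70451856, present in all 4 heat shock lists, chr10:70446094-70446475 had a peak in both KO heat shock lists (scores 314 and 94.1) and in no other. Both regions stood far higher in KO heat shock replicate 1 than in replicate 2 (ranks 12 and 235 for the former, 60 and 555 for the latter). In WT heat shock replicates 1 and 2 the former scored only 73.3 and 84.7. The source of these peaks was not tested. The reverse, a peak in both untreated lists and no heat shock list, was seen at 2 regions, both with low scores: chr10:104403861-104405951 (67.0 in KO and 50.7 in WT) and chrX:136520129-136520842 (75 and 53.1). Chromosome X held 0.105% of the KO regions with a peak in 1 library (6 of 5718) against 2.40% of the regions in 2 or 3 KO lists (17 of 707), and chromosome Y 0.612% against 3.96%.

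WT regions with a peak in 1 library were concentrated on parts of a few chromosomes: chromosome 17 held 43.0% of them (64 of 149), chromosome 10 24.2% and chromosome 8 14.1%. The KO regions with a peak in 1 library were spread more widely. Chromosomes 17, 10 and 8 held 11.1, 8.34 and 3.31% of these, against 9.76, 3.96 and 3.82% of the regions in 2 or 3 KO lists. No share was compared with chromosome length. Extra copies present in both lines, of the kind HCT116 is known to carry, may be one source but stay open: 13 windows of 10 Mb that held at least 4 such WT regions held 19.7% of the KO regions with a peak in 1 library and 13.3% of those in 2 or 3 KO lists (odds ratio 1.60; Fisher's exact test, two-sided, p = 2.38e-05, adjusted p = 5.95e-05 over 10 tests), yet by chromosome the odds ratio was 4.20 on chromosome 10, 1.78 on 16 and 1.39 on 17, and the other way, 0.532 on 8 and 0.423 on 21 (adjusted p from 1.23e-06 on chromosome 10 to 0.0738 on chromosome 8, same exact test). Chromosome 19, rich in genes, held 3.11% of the first set and 7.64% of the second (odds ratio 0.389, p = 4.67e-08 and adjusted p = 4.67e-07 by Fisher's exact test, two-sided). That is lower than was predicted if high gene density were the source. Gene density stays open all the same, since 1 chromosome stood in for it and regions in 2 or 3 KO lists may follow it too. The p-values of Fisher's test in this paragraph treat regions as independent. They cover the spread among regions, and not that between libraries. The first 30 Mb of chromosome 1 held 10.2% of the KO regions with a peak in 1 library (8.83 to 11.2% in each KO list), 6.08% of the regions in 2 or 3 KO lists (odds ratio 1.76; Fisher's exact test, two-sided, p = 2.76e-04, adjusted p = 5.52e-04) and 0.671% of the WT regions with a peak in 1 library (1 of 149; odds ratio 16.9; p = 4.84e-06, adjusted p = 1.61e-05). Most of those WT regions lie in the 13 windows, and outside them the odds ratio was 4.09 (585 of 4589 against 1 of 29; Fisher's exact test, two-sided, p = 0.167, adjusted p = 0.167), so extra copies of the start of chromosome 1 in KO alone are neither shown nor excluded.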
